A study of Mus musculus with 2 samples.

How the data were processed

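H3K36me3, the trimethylated form of lysine 36 of histone H3, was mapped by ChIP-seq in limb tissue of mouse embryos of the B6NCrl strain at 13.5 days of gestation. Per the labels, embryos of both sexes were pooled, and the samples were 2 biological replicates of this 1 tissue and stage, each made of 2 technical replicates that had been put together before peak calling. Nothing else was compared in the labels, so the samples formed 1 group, and replicate numbers were taken from the labels.

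The deposited data were 4 peak lists: 1 for each replicate, 1 called on the pooled replicates and 1 replicated list. Per the deposited description files, reads were aligned to mm10, peaks were called against a control alignment, and the replicated list was derived from the 3 other lists. The peak caller, its thresholds and the rule for the replicated list were not given in the sources used here. For each peak the authors gave a display score, a fold enrichment (a linear ratio) and the offset of the summit from the peak start. They also gave the −log10 of a p-value and of a q-value. The lowest deposited −log10 p was 2.03 in each list. The score and the summit offset that the authors deposited were not used in any result. The authors' fold and −log10 values served to describe, rank or filter peaks within a list, and in the closing section fold was compared between groups of genes within each replicate list. The files hold no read counts, so the sequencing depth of each replicate is unknown, and no interval that needs it was computed.

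Gene models were taken from GENCODE mouse release M21 on GRCm38, whose chromosome lengths match those of mm10. Chromosomes 1 to 19, X and Y were used, and assembly gaps of at least 1 kb were left out of denominators and of random placement, which left 2648 Mb. Coverage of a gene was the percent of its bases, from annotated start to annotated end, that lay inside peaks of a list. A protein-coding gene was called marked when at least 10% of its body was covered in each of the 2 replicates. Peaks of the replicates were counted as overlapping when a single peak of the other replicate covered at least 50% of their length. Observed overlap and annotation shares were set beside 100 random placements of the same peaks within their chromosomes. Profiles used genes of at least 10 kb, divided into 10 equal parts by strand, with flanks of 5 kb. Exons and introns were compared within each gene that had at least 200 bases of each in the part examined.

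Gene lists were 22 lists by name with 637 members, of which 1 (Ahsp) was not found in the annotation, and 4 families chosen by a rule on symbols. For each list the number marked and the median coverage were computed, with percentiles among 10000 random lists of protein-coding genes matched on gene length in 20 bins. Differences between replicates were matched on mean coverage, over members covered in either replicate, for lists with at least 3 of these. The percentiles describe these 2 samples and are not p-values, and genes are not independent replicates. With 1 group of 2 samples no test between groups was possible.

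The lists, the 10% minimum, the overlap rule and the alternatives were fixed before the data were examined. The count of marked members was set against random lists, next to the planned median, after the medians of many lists had been seen to be 0. Genes were named by a fixed rule: in each list the 3 with the highest and the 2 with the lowest mean coverage, ties broken by symbol; 12 limb, muscle and histone methylation genes (Tbx5, Tbx4, Pitx1, Shh, Fgf8, Sox9, Col2a1, Prrx1, Hoxa13, Hoxd13, Myod1 and Setd2); the 10 genes of at least 10 kb with the highest mean coverage; and the 5 such genes with the largest difference in each direction between replicates. The rule also took the 5 longest stretches, after joining peaks within 1 kb, that lay outside any annotated gene in both replicates. Any other gene named was chosen after its values were seen, and the text says so. Coordinates are 1-based and on mm10.

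Alternatives were a minimum −log10 q of 2, the replicated list in place of the replicate lists, each replicate alone, other coverage minimums, joined peaks, other overlap rules, equal numbers of peaks, other gene length limits, lists without length matching and other parts of the gene. Counting only bases that belong to a single coding gene, and only coding members of each list, was added after the data were seen. Errors are SDs over the 2 replicates, and intervals are 95% Wilson intervals that cover counting error only. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data: for 200 genes with peaks placed at known coverage, the largest error was 1.72 percentage points, and of 200 random gene lists 5% fell outside the 2.5th and 97.5th percentiles for marked members. Peaks on scaffolds outside these chromosomes entered only the peak counts, overlap shares and list lengths.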

Results

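The data described where H3K36me3, a histone mark laid down over the bodies of transcribed genes by the methyltransferase Setd2, lay in the limb of the mouse embryo at 13.5 days, a stage at which cartilage models of the limb bones and the digits are forming. The list of replicate 1 held 215766 peaks over 137 Mb, 5.17% of the genome, and that of replicate 2 held 195278 peaks over 133 Mb, 5.03%. Median peak length was 371 bp in replicate 1 and 397 bp in replicate 2. Sequencing depth is unknown from the peak lists, so a gene without peaks was one in which no enrichment was called, not one shown to lack the mark.

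H3K36me3 peaks lay almost wholly inside protein-coding genes. Coding gene bodies held 94.1% ± 0.198 (SD, n = 2) of peak bases, against 41.9% for randomly placed peaks, a 2.24-fold excess. The 5 kb after gene ends held 4.21% ± 0.0327, 1.5-fold more than random placement. Bases in the 2 kb before gene starts that lay in no gene and in no stretch after a gene end held 0.0188% ± 0.00251, against 1.08% for random placement. Other annotated genes held 1.05% ± 0.0321, and the rest of the genome held 0.623% ± 0.131 against 47.3% at random. Of 5854 lincRNA genes 183 were marked, and of the 5358 that overlapped no coding gene 84, or 1.57%, were marked.

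In all, 8803 of 21938 protein-coding genes (40.1%) were marked, and 9712 (44.3%) had no peak base in either replicate. Of the marked genes 3390 were covered over at least 50% of their length in both replicates. The most covered genes of at least 10 kb were led by Sf3a1, a subunit of the splicing factor SF3a (chromosome 11, 4160350 to 4182541), at 93.3% ± 0.934, and by Phykpl at 92.4% ± 0.168, of whose body 22.2% is shared with Hnrnpab. Next came the ubiquitin ligase gene Rnf40 at 92.0% ± 1.12, the exosome subunit Exosc10 at 91.9% ± 1.17, the acetyltransferase scaffold Trrap at 91.8% ± 0.104 and the corepressor Sin3b at 91.4% ± 0.456. Prr12, the glycolytic enzyme gene Gpi1, the Integrator subunit Ints1 and the polarity gene Scrib lay between 90.7% and 91.3%. Marked genes made up 52.6% of genes between 30 and 100 kb, but 3.07% of genes under 1 kb and 28.0% of genes over 100 kb, and gene lists were compared with genes of matched length.

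Coverage rose from the first part of the gene to the ninth and was slightly lower in the last. In 6715 marked genes of at least 10 kb, divided into 10 equal parts, the first part was covered over 7.82% ± 0.209 of its bases, the second over 25.9% ± 0.643, the fifth over 46.5% ± 0.163 and the ninth over 62.0% ± 0.0637. The last part was at 59.9% ± 0.134, a ratio of 7.67 ± 0.188 to the first, and the 5 kb beyond the gene end at 28.7% ± 0.306. The 5 kb before the gene start, counted with any other genes there, was at 7.71% ± 0.118, close to the first part. Col2a1 showed this shape at a single gene: peaks were nearly unbroken toward its 3' end and stopped short of its start. In marked genes of at least 30 kb the ratio of the last to the first part was 4.73, and the direction was kept.

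**Figure D1:**
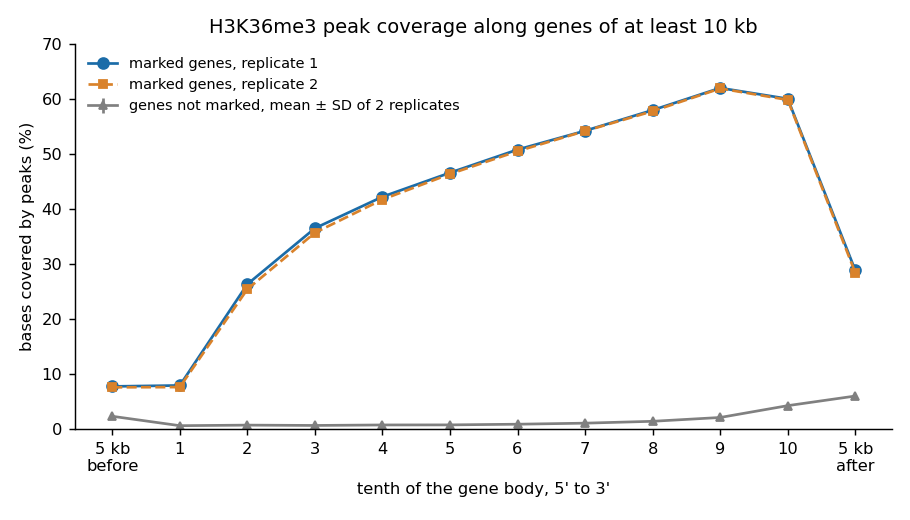
Percent of bases covered by H3K36me3 peaks (vertical axis) in the 5 kb before the gene, in each of 10 equal parts of the gene body and in the 5 kb after it (horizontal axis), for 6715 marked genes in each replicate and for 7449 genes that were not marked (mean ± SD of 2 replicates). Coverage of marked genes climbed from 7.82% in the first part to 62.0% in the ninth. Genes that were not marked stayed at or below 4.30% inside the gene. By definition they were covered below 10% in at least 1 replicate, so this low level follows largely from their selection.

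Peaks covered a larger share of exonic than of intronic bases of the same genes. Over the 3' 50% of 6663 marked genes, exonic bases were covered at 66.5% ± 0.0766 and intronic bases at 55.1% ± 0.124, a difference of 11.5 ± 0.0472 percentage points, and exons were higher in 69.8% of these genes. Without the last 10% of the gene the difference was 16.8 ± 0.0497 points, and over the 5' 50% it was 4.04 ± 0.341 points. Exons remained higher on average in each of these parts, by more than the spread between replicates. Over the 5' 50%, however, exons were higher in 51.0% of genes and lower in 44.6%. Position within a part was not matched, and coverage of marked genes itself rose from 50.7% in the sixth of the 10 parts to 62.0% in the ninth. The share of the difference that comes from position is therefore not known.

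Genes for limb identity and growth ranged from no coverage to above 50%. Of 56 limb mesenchyme and patterning genes 17 were marked, against a mean of 23.1 in random lists matched on length (4.56th percentile, inside the central 95%). The list's place depended on the minimum: 29 were marked against a mean of 25.7 at a minimum of 5% covered, and 3 against 8.64, below the central 95%, at 50%. The Hedgehog receptor gene Ptch1 (chromosome 13, 63508328 to 63573598) was covered at 54.5% ± 0.664 and the Hedgehog effector gene Gli1 at 52.2% ± 0.795. Tbx4, the hindlimb T-box gene (chromosome 11, 85886422 to 85916097), was covered at 52.8% ± 1.97, and Tbx5, its forelimb counterpart (chromosome 5, 119832668 to 119885219), at 41.3% ± 3.67. Prrx1, a homeobox gene of limb mesenchyme, was at 36.8% ± 2.49, whereas the hindlimb gene Pitx1 was at 7.39% ± 0.850 and not marked. No peak base lay in Shh or Fgf8, the signal genes of the zone of polarizing activity and the apical ectodermal ridge, nor in Alx1 or Dlx6. The labels do not say whether forelimbs, hindlimbs or both were taken.

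The Hox genes were counted in separate lists, and the difference between these lists was not tested. Of 20 genes of the A and D clusters, which pattern the limb, 5 were marked against a mean of 6.04 in random lists (30.8th percentile). These were Hoxa9 at 28.3% ± 3.74, Hoxa5 at 22.8% ± 12.8, Hoxa10 at 22.2% ± 2.16, Hoxd13 at 20.8% ± 5.46 and Hoxd10 at 17.8% ± 10.9, the last named because it completes the count. Hoxd10 was covered at 10.1% in replicate 1, just past the minimum, and at 25.5% in replicate 2. Hoxa5 lies wholly within the annotated Hoxa3, so its peaks cannot be assigned to it alone. Hoxa13 was covered over 7.91% of its length in replicate 1 and had no peak base in replicate 2, and Hoxa1 and Hoxa11 had none in either. Of 19 genes of the B and C clusters none was marked against a mean of 6.53 (0.02nd percentile), and the highest, Hoxc4, was at 0.536% ± 0.758. Hoxb1 and Hoxb13 had no peak base. At a minimum of 25% covered both lists lay below random lists, with 1 gene of the A and D clusters marked, and at 50% neither did.

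**Figure D2:**
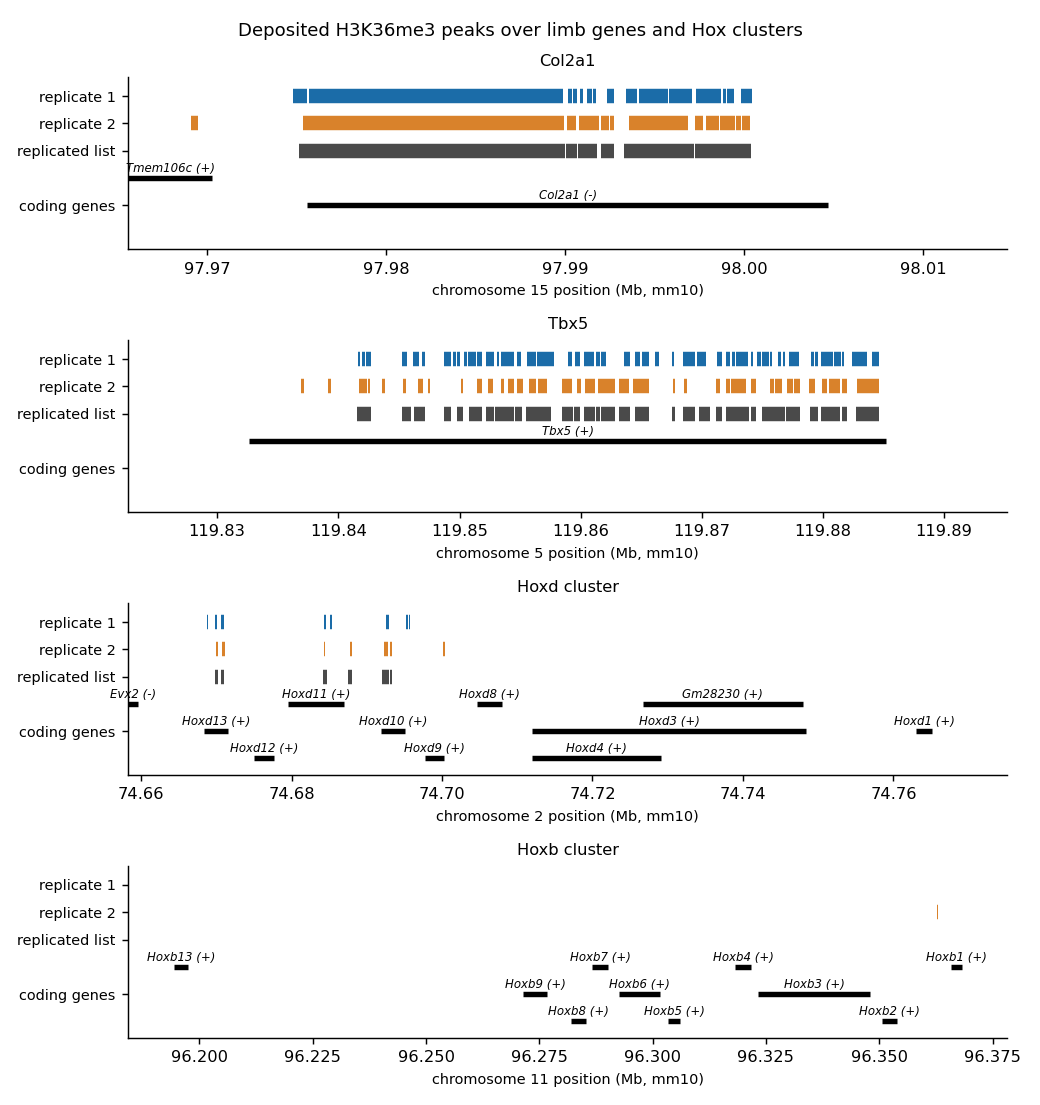
Deposited peaks of replicate 1, replicate 2 and the replicated list (colored blocks) above coding genes (black bars, strand in brackets) at Col2a1, Tbx5, the Hoxd cluster and the Hoxb cluster, each with 10 kb on either side. The horizontal axis is the mm10 position in Mb. Col2a1 was covered over 76.0% and Tbx5 over 41.3% of its length, the Hoxd cluster held short blocks such as those at Hoxd13 (20.8%), and no Hoxb gene was marked.

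Cartilage and matrix genes included some of the most covered tissue genes. Of 30 chondrogenesis genes 12 were marked, close to the mean of 11.8 in random lists (54.0th percentile). Col27a1, a fibrillar collagen gene of cartilage, was at 77.2% ± 0.740, and Col2a1, the main cartilage collagen gene (chromosome 15, 97975602 to 98004695), at 76.0% ± 2.41. Fgfr3, the growth factor receptor gene of growth cartilage, was at 54.7% ± 2.16, and Sox9, the master regulator of cartilage, at 25.3% ± 1.65. Ihh and Barx1 had no peak base. Of 23 tendon and connective tissue genes 14 were marked against a mean of 9.53 (97.2nd percentile), with fibronectin Fn1 at 88.1% ± 1.24, Col6a1 at 79.2% ± 0.765 and Fbn2 at 70.4% ± 1.35. This list lay above the central 95% of random lists under several alternatives, with 16 members marked in each replicate alone. Egr1 had no peak base, nor had Scx, the tendon regulator gene, which lies wholly within the annotated Bop1.

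Of 16 osteogenesis and hypertrophy genes 3 were marked against a mean of 6.17 in random lists (4.78th percentile, inside the central 95%). Col1a1 was at 82.0% ± 0.517 and Col1a2 at 73.3% ± 0.556, the genes of the chains of type I collagen. Col10a1, the marker of hypertrophic cartilage, was at 19.8% ± 5.24 and lies wholly within Nt5dc1. The alkaline phosphatase gene Alpl and the osteocalcin gene Bglap had no peak base.

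Markers of the minority cell types of the limb were marked less often than genes of the same length. Of 35 myogenesis genes only Six4, at 46.5% ± 2.71, was marked, against a mean of 13 in random lists (percentile 0). Ryr1 was at 6.31% ± 2.95 and Cdh15 at 4.39% ± 2.16, the latter within the annotated Gm20388, and Myod1, Acta1 and Actc1 had no peak base. Of 23 endothelial genes the Ets-family genes Fli1, at 23.6% ± 0.199, and Ets1, at 12.1% ± 1.75, were marked (0.025th percentile). Erg was at 9.39% ± 0.189, and Cdh5 and Cldn5 had no peak base. Of 20 erythroid genes the transferrin receptor gene Tfrc, at 48.6% ± 3.28, and Nfe2, at 13.3% ± 0.923, were marked (0.55th percentile). Alas2, which lies within the annotated Apex2, was at 9.92% ± 0.541, and Gata1 and Ank1 had none.

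Of 21 leukocyte genes 3 were marked (1.04th percentile). Cd68, a gene of 1.94 kb, was at 96.9% ± 4.44, Fcer1g at 18.5% ± 2.58 and Cx3cr1, whose annotated body shares 53.2% with other coding genes, at 18.5% ± 0.248. Neighbouring genes that do not overlap were not examined, and the 5 kb after the ends of marked genes was covered at 28.7% ± 0.306. Peaks in the short genes Cd68 and Fcer1g were therefore not assigned to these genes alone. Adgre1 and C1qa had no peak base. Of 25 surface ectoderm genes 2 were marked (0.07th percentile), Esrp2 at 41.1% ± 9.60 and Krt18 at 15.7% ± 3.82. Esrp2 shares 3.29% of its body with Nfatc3. Genes beside these 2 short genes were not examined either, so their peaks were not assigned to them alone. Dsp was at 3.75% ± 0.818, and Cldn4 and Cldn6 had none. None of 15 neural crest, Schwann and melanocyte genes was marked (0.01st percentile). S100b came nearest with 8.31% in replicate 1 and 20.1% in replicate 2, Erbb3 was at 6.81% ± 3.20 and Pmel at 2.61% ± 1.43, and Cdh19 and Egr2 had none. S100b shares 23.7% of its body with Dip2a, so its peaks cannot be assigned to it alone.

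Markers of tissues outside the limb were almost free of peaks. None of 31 neuronal, 25 liver, 20 heart or 25 germline genes was marked, against means of 11.1, 10.7, 7.77 and 10.4 in random lists, each at percentile 0. All 20 heart genes, among them Gata4, Gja5 and Hcn4, had no peak base. The highest neuronal gene, Celf4, was at 0.405% ± 0.337, followed by Elavl3 at 0.124% ± 0.176 and Grin2b at 0.0750% ± 0.0335, with none in Camk2a or Elavl4. Among liver genes Hnf1a was at 6.45% ± 0.393 and F2 at 0.410% ± 0.580, and Afp and Ahsg had none. Among germline genes Sycp3, within Chpt1, was at 2.63% ± 1.59, Dazl at 0.994% ± 1.41 and Dmc1 at 0.978% ± 0.783, and Acrv1 and Bmp15 had none. Of 20 intestine and pancreas genes only the lactase gene Lct was marked, at 11.4% ± 0.547, just past the 10% minimum. Genes beside Lct were not examined, so its peaks were not assigned to it alone. Vil1 was at 4.32% ± 0.632 and Cpa1 at 1.46% ± 2.07, and Alpi and Amy2b had no peak base.

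Genes of growth and of the basic machinery of the cell were marked far more often than genes of the same length. Of 77 ribosomal protein genes 69 were marked, with a median coverage of 56.0% ± 0.0128, of 31 proteasome genes 30, at 61.9% ± 1.11, and of 41 DNA replication and cell cycle genes 40, at 65.7% ± 0.524. Random lists had means of 20.1, 13.9 and 18.7 marked genes, and each of these lists lay at percentile 100. Rps15a was at 83.8% ± 1.42, Rps5 at 79.5% ± 2.40, Rpl26 at 78.9% ± 4.01, Psmc4 at 86.2% ± 2.37, Psmc3 at 84.3% ± 1.79 and Psmd2 at 77.6% ± 2.86. Psmc3 shares 37.0% of its body with Slc39a13. The helicase genes Mcm5, Mcm2 and Mcm3 were at 87.3% ± 0.101, 84.8% ± 1.78 and 84.1% ± 0.607. The exceptions among the proteasome and replication genes were Psmd14, at 7.16% ± 2.10 over 88.7 kb, and the X-linked polymerase gene Pola1, at 1.76% ± 0.148 over 327 kb. Psma2 was at 18.6% ± 1.82 and Prim2 at 11.6% ± 1.25. The short ribosomal genes Rpl36 and Rps21 were at 0 and 2.29% ± 3.24.

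Genes for writers, readers and demethylases of H3K36 methylation and for proteins that work with them were marked in 24 of 25 cases, against a mean of 12.4 (percentile 100), with a median of 52.2% ± 0.115. The demethylase gene Kdm4a was at 90.2% ± 0.139, Supt6 at 78.9% ± 0.532, Brpf1 at 75.3% ± 0.746 and Setd2 (chromosome 9, 110532597 to 110618633) at 57.3% ± 0.503. Setmar was at 12.9% ± 2.72, and Phf19 had no peak base. Of 38 imprinted genes 23 were marked against a mean of 14.9 (99.7th percentile), but 7 of them are noncoding and random lists held coding genes only. Of the 31 coding members 17 were marked against a mean of 11.8, still above the central 95%, while their median coverage lay inside it, at a mean percentile of 94.1. Igf2r was at 65.6% ± 1.51, while Mcts2 at 100% and Nnat at 72.1% ± 0.0578 lie within H13 and Blcap, and Ascl2 and Ddc had no peak base. With bases of a single coding gene counted alone, the percentile of the imprinted list's median was 92.9, inside the range of random lists. At a minimum −log10 q of 2, or at a minimum of 50% covered, the number of marked imprinted genes was also inside that range.

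Large gene families differed sharply. Of 418 zinc finger genes 305 were marked against a mean of 196 (percentile 100), with a median coverage of 34.9% ± 0.227. Zfp869 was at 95% ± 2.24, Zfp335 at 88.2% ± 0.523 and Zfp865 at 87.9% ± 1.16, the last sharing all its bases with neighbouring gene models, and Zfp185 and Zfp345 had no peak base. None of 1093 olfactory receptor genes and none of 327 vomeronasal receptor genes was marked, against means of 351 and 124 in random lists (percentile 0 for each). In these families Olfr267 was at 2.5% ± 3.54 and Vmn1r90 at 3.12% ± 1.15, and Olfr1, Olfr10, Vmn1r1 and Vmn1r10 had none. None of 66 replication-dependent histone genes was marked either, against a mean of 5.52 (0.105th percentile), although replication genes were. Hist1h2ba was at 2.47% ± 3.50 and Hist1h2bc at 1.23% ± 1.75, and Hist1h1a and Hist1h1b had no peak base.

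By the planned measure, the median coverage of a list, 6 of the 26 lists lay above the central 95% of random lists in both replicates: ribosomal, proteasome, replication, H3K36 methylation, imprinted and zinc finger genes. No list lay below it by its median, and for 17 of the lists that median was itself 0. For these 17 the median could not fall below the central 95%, because 0 is the lowest value and tied with many random lists. By the number of marked members, the measure added later, 15 lists lay below the central 95% of random lists and the same 6 above it. At a minimum of 50% covered 11 lists lay below it, without Hox B and C, leukocyte, neural crest, intestine and pancreas, and histone genes and with limb genes.

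**Figure D3:**
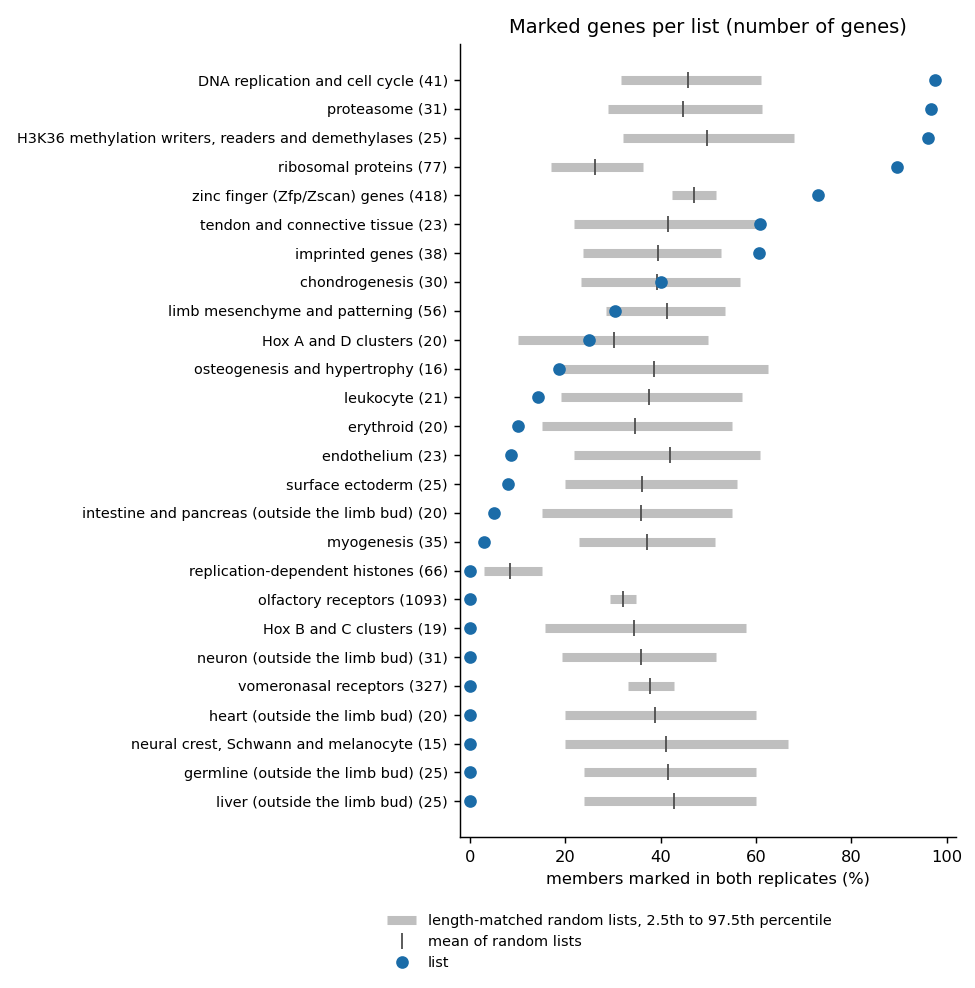
Percent of members marked in both replicates (points, horizontal axis) for each of the 26 gene lists (vertical axis, number of genes in brackets), with the mean (ticks) and the central 95% (bars) of 10000 length-matched random lists. Replication, proteasome, H3K36 methylation, ribosomal, zinc finger and imprinted genes lie to the right of their bars, and 15 lists lie to the left.

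Called peaks covered far less of the X chromosome than of the autosomes. They covered 0.836% ± 0.0195 of the X and 5.58% ± 0.107 of the autosomes, and chromosome 11 was highest at 9.09% ± 0.0975. Of 948 X-linked coding genes 143 (15.1%) were marked, against 8660 of 20807 autosomal genes (41.6%) and a mean of 356 in random autosomal sets of the same lengths. The planned measure, the median coverage of X-linked genes, was 0 in both replicates and lay at the 11.3th and 30.7th percentiles of these sets, not outside their range. A median of 0 is the lowest possible and tied with many random sets, so this measure could not place the X below them. Within coding genes alone 2.73% ± 0.0623 of X bases were covered. None of 183 genes on the Y chromosome was marked. Read depth and read mapping on the Y are not known here, so these genes were not shown to lack the mark. Pola1 and Alas2, not marked, and Cdk16, at 44.9% ± 12.2, are X-linked. The pools held embryos of both sexes.

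**Figure D4:**
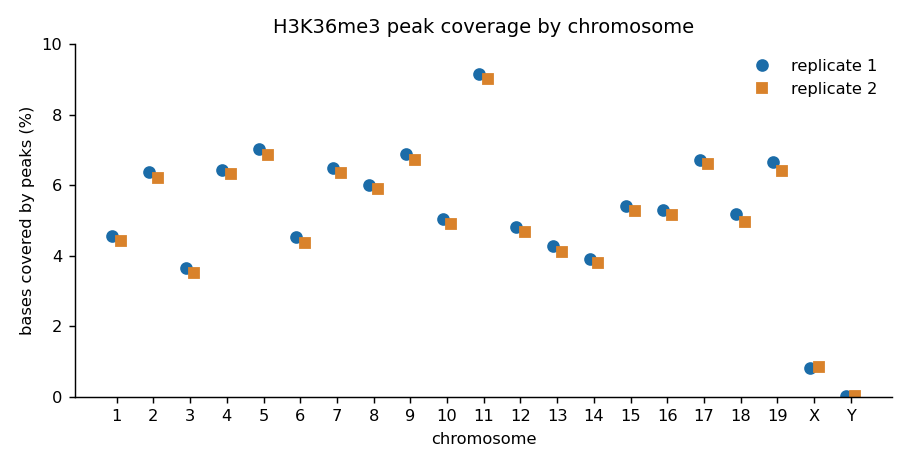
Percent of bases covered by H3K36me3 peaks (vertical axis) on each chromosome (horizontal axis) in replicate 1 and replicate 2. Chromosome 11 is highest at 9.09%, while the X at 0.836% and the Y at 0.00961% lie below every autosome.

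The replicates differed little at the level of genes. Coverage correlated across 21938 coding genes with Pearson r = 0.990 and Spearman rho = 0.976, where genes are not independent replicates. Mean coverage was 18.8% in replicate 1 and 18.6% in replicate 2, and the SD of the difference between replicates was 3.61 percentage points. The 10% minimum was reached in replicate 1 alone by 286 genes and in replicate 2 alone by 178. Differences above 20 points were found at 50 marked genes, all shorter than 10 kb. Among genes of at least 10 kb, the largest differences toward replicate 1 were at Adamts4, a matrix protease gene (45.5% and 26.2%), Mtrf1 (40.7% and 23.9%), Sars2 (57.8% and 41.5%), Coa7 (54.9% and 38.9%) and Ccdc32 (47.2% and 31.3%). Among the same genes, those toward replicate 2 were at Slc35f6 (41.0% and 58.9%), Cdk16 (36.3% and 53.5%), Rps6ka4 (39.3% and 56.3%), Slc12a9 (39.1% and 54.5%) and Polm (49.7% and 65%).

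Of 20 lists with enough covered members, 2 differed between replicates outside the central range of random lists. In the simulated data 4.5% of 200 random lists also lay outside that range for differences. Hox A and D genes were higher in replicate 1 by a median of 3.05 points over 11 covered members (99.5th percentile), and chondrogenesis genes had a median difference of -0.419 points (1.58th percentile). The marked Hox genes went both ways: Hoxa9, Hoxa10 and Hoxd13 were higher in replicate 1, and Hoxa5 and Hoxd10 in replicate 2. At a minimum −log10 q of 2, neither list lay outside it, at percentiles of 31.7 and 20.

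Individual peaks overlapped less completely than gene coverage did. Of the peaks of replicate 1, 61.9% (95% Wilson interval 61.7% to 62.1%) were overlapped over at least 50% of their length by a peak of replicate 2, 12.2-fold more than random placement. In the other direction the share was 65.6% (65.3% to 65.8%), 13-fold more. The lists shared 105 Mb, a Jaccard index of 63.5% against 3.01% at random. Random placement was over whole chromosomes, whereas 94.1% of peak bases lay in coding genes. The excess over random placement therefore does not separate agreement of single peaks from location in the same genes. All 141566 peaks of the replicated list were identical to peaks of the pooled list, of which they made up 66.9%. Ranked by the authors' −log10 p, 100% of the strongest 10% of pooled peaks, 88.6% of the fifth group of that size and 7.85% of the weakest were in the replicated list. Of the 121058 pooled peaks that overlapped a peak in each replicate 99.3% were kept, and of the 90408 others 23.6%.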

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

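The tests in this part were written down before their results were seen, except for the spacing of fold values on the X, which was examined after the test it bears on. The deposited lists also held peaks on scaffolds outside the chromosomes analysed, which entered no comparison between genes: the replicated list had 22, the pooled list 57. No control was available to set them against.

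Zinc finger genes were marked in 305 of 418 cases, 26.1 percentage points above genes of matched length. Reads shared between neighbouring paralogs were weighed first: the 109 zinc finger genes with no other member of the list within 1 Mb still lay 30.2 points (binomial SE 4.18) above matched genes. This argues against neighbours in the list as the whole source. The list was chosen by symbol, so nearby paralogs with other symbols were not counted. A general property of marked genes was weighed next. The median of the strongest fold per marked zinc finger gene lay at percentile 100 of marked genes matched on coverage in both replicates, at 6.49 against 5.72 in replicate 1, so these genes stood apart in strength as well. Reads shared with distant paralogs, or with nearby ones outside the list, remain open, and since the design holds 1 tissue and stage, no biological explanation was tested.

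Exons were covered 11.5 percentage points more than introns in the 3' 50% of marked genes. If repeats in introns, where reads may map poorly, were the source, the difference would fall below 50% of its size outside repeats, and it was 9.91 ± 0.115 points there. If GC content were the source, the difference would fall below 25% of its unbinned size within bins of GC content. In windows of 200 bases it was 11.2 ± 0.0828 points within bins and 11 ± 0.0293 without binning. Mean GC content differed little, at 45.8% in exon windows and 44.0% in intron windows. The difference outside repeats and that within GC bins argue against these explanations as the whole cause. How well short reads map to each base was not analysed here, nor was position within the 3' 50%, along which coverage rose. No biological explanation was tested.

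Predicted and RIKEN gene models do not account for the lower marked share of X-linked genes: without the 156 such genes on the X, the marked share still lay at -21.8 points (binomial SE 1.35) relative to matched autosomal genes. Lower read depth on the X could also be the source, and the ratio of the 95th percentile of peak fold in X-linked to autosomal marked genes was 0.737, where a value above 0.9 had been set for equal enrichment. A check chosen after that ratio was seen put the bound in doubt: within 0.01 of a step, 90.6% of X-linked and 56.7% of autosomal fold values in replicate 1, and 82.8% and 50.2% in replicate 2, lay on a grid of equal steps, though a first form of the check without an offset did not show the steps in replicate 2. Such steps would arise if reads were divided by a background shared by the genome, in which case fold itself would fall with the depth of the X. Lower depth and lower enrichment of the X therefore cannot be told apart here, and no biological explanation was tested.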

How the results depend on the processing

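The alternatives were fixed before the data were examined, except the count of marked members, the count over bases of a single coding gene and lists of coding members only, which were added afterwards. No paired analysis was possible because all samples formed 1 group. The share of peak bases in coding genes (94.0% to 94.3%) kept its value. The profile, exon and X results kept their direction. Lists below random lists by marked members numbered 11 to 16, and those above 6 or 7. Marked genes numbered 6716 to 9676 elsewhere but 3390 at a minimum of 50% covered, where a higher minimum leaves fewer genes by construction. For the changes below the cause was not tested. Sequencing depth limits weakly marked genes, and it is not known here.

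With peaks of −log10 q of at least 2, the ratio of the last to the first 10% of the gene was 8.15, the exon minus intron difference 11.6 points, X coverage 0.739%, and the gene correlation 0.989. Overlap was then 61.6% for replicate 1 and 67.7% for replicate 2, and 0 gene lists differed between replicates. With the replicated list the ratio was 7.47, the exon difference 11.6 points and X coverage 0.986%. Each replicate alone gave an exon difference of 11.59 to 11.62 points, and for the profile 7.57 to 7.80. The ratio was 4.73 in genes of at least 30 kb. The exon difference was 16.8 points without the last 10% of the gene and 4.04 over the 5' 50%. X coverage was 2.73% over coding genes.

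The gene correlation was 0.995 in genes of at least 10 kb and 0.982 in genes covered in either replicate. For replicates 1 and 2, overlap was 74.9% and 80.5% with at least 1 base, 44.0% and 48.6% with 50% of both peaks, 65.04% and 63.5% with equal numbers of peaks, and 68.7% and 66.4% in the stronger 50% of those. At equal covered length 1 gene list differed between replicates.

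Some lists inside the central range, or differing between replicates, changed sides of random lists. Marked limb genes numbered 29 (above) at a minimum of 5% covered, Hox A and D genes 7 with the replicated list, and chondrogenesis genes 8 and 3 (below) at minimums of 25% and 50%, and 12 (below) without length matching. With each replicate alone they numbered 12 to 14, and only the 12 without replicate 2 lay below. The median percentile of Hox A and D genes was 52.8 in genes of at least 5 kb. At −log10 q of at least 2, percentiles of the difference were 31.7 for Hox A and D, 38.3 for osteogenesis, 65.8 for tendon, 61.1 for germline, 50.4 for H3K36 methylation, 38.2 for imprinted and 27.6 for zinc finger genes. At equal covered length they were 8.46 for limb and 48.7 for endothelial genes.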

Other observations

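The tallies in this part were chosen after the data were seen, apart from the stretches outside genes. The strongest peaks were concentrated in zinc finger genes. Of the 100 peaks with the highest −log10 p, 52 in replicate 1 and 46 in replicate 2 lay in genes of the zinc finger list, which held 1.91% and 1.96% of all peaks. The strongest of replicate 2 lay over Zfp810 (chromosome 9, 22276690 to 22281186) with a fold of 21.4, followed by the Zfp865 locus at 20.7 and Zfp354c at 20.0. In replicate 1 the peak over Zfp157 had a fold of 16.2. These genes, apart from Zfp865, were chosen after their values were seen.

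The strongest peak of replicate 1 by −log10 p lay elsewhere, on the X chromosome (169988471 to 169989577) within Mid1, with a fold of 8.14 and a length of 1107 bp. It ranked 4th in replicate 2, with a fold of 9.48. Whether the reads at this peak come from the X alone was not examined, so it was not set against the coverage of the X.

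Few marked stretches lay outside annotated genes. After peaks within 1 kb were joined, 1698 stretches found in both replicates, 1.29 Mb in all, touched no annotated gene, and 13 of them were at least 5 kb long. The longest was on chromosome 10 (79051061 to 79060124, 9.06 kb), covered over 63.9% in replicate 1 and 48.9% in replicate 2, with 2610008E11Rik as the nearest coding gene on its right side. The next were on chromosome 2 (84585969 to 84594338, beside Ctnnd1), chromosome 5 (104581070 to 104589071) and chromosome 17 (3069062 to 3076320). The fifth, on chromosome 2 (52122397 to 52129192), began 0.013 kb beyond the annotated end of Rif1.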
